A study of Rattus norvegicus with 8 samples.

How the data were processed

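Total RNA from livers of male Sprague-Dawley rats was labelled with biotin and hybridized to Affymetrix arrays, per the labels' protocols. The table holds 8 arrays, 4 control and 4 hydrogen water, and each column was assigned to its group through its label. The values are intensities on a linear scale, all above 0, and the authors made them with MAS5, per the submitters' processing notes. MAS5 is the Affymetrix algorithm that subtracts background and combines the probe pairs of a probe set into 1 signal. Its version, the scaling target and the detection calls are not given in the sources used here. Without detection calls, low signals cannot be set apart from background, so a filter on the mean signal was used.

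The arrays carried no common scale: their medians ran from 17.2 to 26.8 and their 2% trimmed means from 80.3 to 132. The design written before the data were examined took MAS5 values as already scaled and planned no further normalization. The array medians showed otherwise, so quantile normalization, planned as an alternative, was made the main setting before any test was run, and the unnormalized fit is given as an alternative. After quantile normalization the distribution of signals is the same on each array, so that a shift of most transcripts in 1 direction would not be seen. A pseudocount of 2.05 (10% of the median of all values, 20.5) was added before taking log2, so fold changes are on the log2(signal + pseudocount) scale and understate the change of dim probe sets. The 57 control probe sets were left out of tests, and the 15521 of 31042 other probe sets with a mean log2 signal at or above the median were kept.

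Gene names came from the platform annotation, with symbols checked by Entrez ID against the RefSeq gene table of the rat assembly GRCr8. A single symbol was held by 20826 probe sets, for 14217 genes, several by 436, and 9780 are unnamed here. Of the 20826, 20758 matched the RefSeq table, and 0 symbols changed. Probe sets with several symbols were tested but not named. Probe set names that end in _a_at, _s_at or _x_at mark probes that can bind several transcripts. Genes without a named probe set were not analysed here. The annotation gives no coordinates that were used.

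Groups were compared per probe set with lmFit and eBayes (trend = TRUE) of limma 3.58.1 in R 4.3.3, with no covariate and Benjamini-Hochberg adjustment over the tested probe sets, at a threshold of 0.05. Prior degrees of freedom were 4.90. Each error given as SE for the change of a probe set comes from this fit, unless a covariate is named. The SE of a gene index, of the Gapdh ratio or of a contrast of signal levels comes from the spread over arrays within each group. Control probe sets were compared with an exact two-sided permutation test over 70 arrangements, whose smallest p is 0.0286. Principal components were taken on centred log2 values.

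Before the data were examined, 34 gene lists were fixed from general knowledge of liver metabolism, redox and stress responses, the clock and cell type markers. They were tested with limma camera at a preset correlation of 0.01 on 9106 genes, each represented by its probe set with the highest mean, and with camera at an estimated correlation and fry as alternatives. The 30 lists with at least 5 measured genes were tested. The lists for adipocytes, with 3 measured genes, and for neutrophils, exocrine pancreas and skeletal muscle, with 1 each, were not. The lists share some genes, and the 14 lists whose members are named were picked after the results were seen.

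The named genes followed a rule fixed before the data were examined. It takes the 12 largest rises and the 12 largest falls among probe sets with 1 symbol, past the threshold and without overlap between groups, each gene once. Of each list described, it takes up to 4 members in order of p. Sod1, Sod2, Cat, Gpx1, Gsr, Hmox1, Nqo1 and Cyp7a1 are given whatever their result. Dusp6, Egr1, Jun, Bmal1 and Dbp lie outside that rule and were chosen after their values were seen.

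The alternatives planned were no normalization, median centring, cyclic loess, no pseudocount, a pseudocount of 50% of the median, no filter, a filter that leaves out 75% of probe sets, no trend in the prior, array weights, the replicate number as a block, gene means, a threshold of 0.10, a minimum fold of 1.2 (treat), a rank product over 16 pairs of arrays with 100 permutations, and leaving out each array. Scaling by the trimmed mean and by 18 spike-in probe sets was added after seeing the data.

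The steps were tested on simulated data with the levels and spreads of the 15521 probe sets of this comparison, 10 draws with 200 changed probe sets each. The limma fit found 35.2% of changes of 1.5-fold, 72.6% of 2-fold, 93.6% of 3-fold and 95.6% of 4-fold, and 4.99% of its calls were false. With no change planted, at most 1 probe set passed in a draw. Camera found a list shifted by 0.3 in 10 of 10 draws and called 0 other lists, on genes simulated as independent. The rank product, run on 3 draws, found 100% of 4-fold changes, but 35.6% of its calls were false. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.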

Results

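Hepatic gene expression was profiled in male Sprague-Dawley rats, an outbred laboratory strain, that had drunk either sterilized distilled water or hydrogen water for 4 weeks. Hydrogen water is drinking water in which molecular hydrogen is dissolved, here at 0.7 mM. The rats were 8 weeks old. The study kept 8 animals per group, and 4 oligonucleotide arrays per group, control and hydrogen water, were analysed here. The labels do not say which animal each array represents or whether RNA was pooled, so the p-values measure the spread between these arrays. The comparison asks which liver transcripts differ after the animals drink hydrogen water.

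Each array gave a signal for 31099 probe sets, short groups of probes directed at a transcript. The median deposited signal ran from 17.2 to 26.8 over the 8 arrays. The control arrays were brighter, with a 2% trimmed mean signal of 115 ± 18.7 (SD, n = 4) against 91.5 ± 10.4 (SD, n = 4) for hydrogen water (p = 0.114, exact two-sided permutation test). The hybridization spike-ins, bacterial and phage transcripts added to the labelled RNA, moved the same way, from a mean log2 signal of 9.44 ± 0.30 (SD, n = 4) to 9.05 ± 0.08 (SD, n = 4; p = 0.0857, exact two-sided permutation test). The log2 ratio of the 3′ to the 5′ probe sets of Gapdh, a sign of RNA integrity, was 0.22 ± 0.10 in controls and 0.38 ± 0.08 in hydrogen water (SD, n = 4 each; p = 0.0571, exact two-sided permutation test). The same ratio for beta-actin differed by 0.04 (p = 0.343, exact two-sided permutation test). The arrays were quantile-normalized before any comparison, and their number limits the precision.

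**Figure D1:**
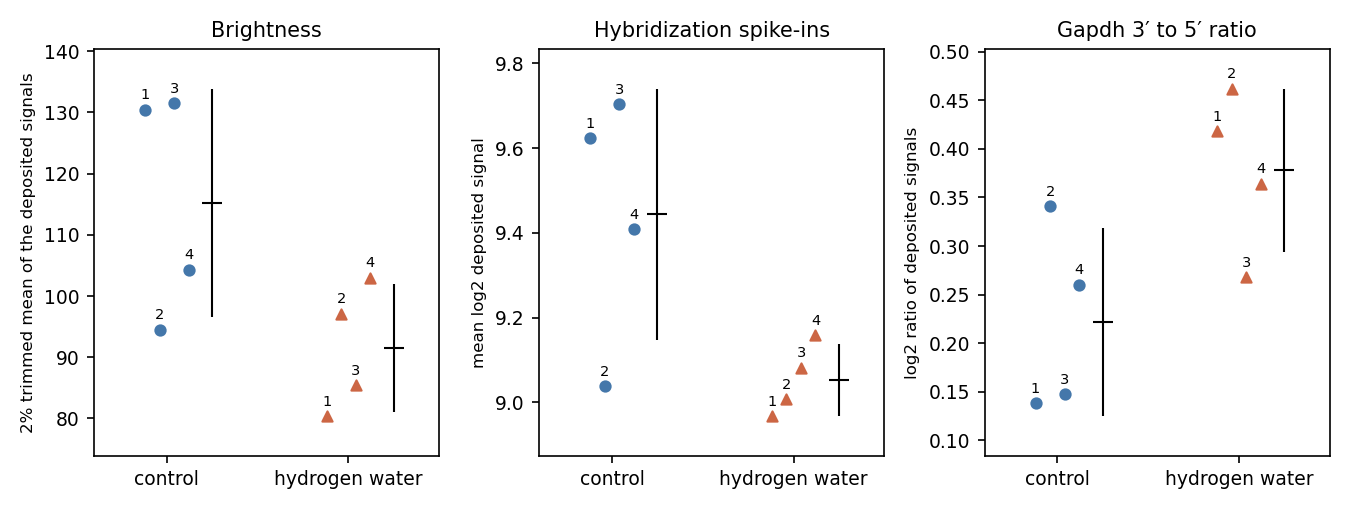
Brightness, spike-in level and Gapdh 3′ to 5′ ratio of each array (points, numbered by replicate) in the control and hydrogen water groups, with the group mean and SD (bars); the vertical axes do not start at 0. The mean spike-in signal was 9.44 in controls and 9.05 in hydrogen water on the log2 scale, and the groups overlap in all 3 panels.

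Livers of rats given hydrogen water differed from control livers most at Cish, an inhibitor of cytokine and growth hormone receptor signalling that is itself induced by STAT5. Cish was at least 12.8-fold lower with hydrogen water, a lower bound because its signal there lay below the median of all values and cannot be set apart from background. The transcription factor Myc fell 4.95-fold and the homeobox factor Hhex 3.95-fold. In the other direction, Fkbp5, a co-chaperone of steroid hormone receptors and a well-known glucocorticoid target, rose 6.63-fold. Nr1d1, the clock repressor REV-ERB alpha, rose at least 3.97-fold, from a control signal also below that median. In all, 128 of 15521 tested probe sets passed an adjusted p of 0.05 in limma, 69 higher and 59 lower with hydrogen water, and 1946 had an unadjusted p under 0.05. Of the 128, 97 carried a single gene symbol, for 43 genes that rose and 45 that fell, and 31 carried none or several. The groups did not overlap at 7.48% of all tested probe sets, against 2.86% by chance. A change of 2-fold or more was seen at 56 of the 128, 33 higher and 23 lower. The first principal component held 26.1% of the variance and separated the groups (p = 0.0286, exact two-sided permutation test, the smallest that 70 arrangements allow). Without normalization between arrays 505 probe sets passed, 21 higher and 484 lower, a share of 4.16% higher against 53.9% in the normalized arrays, and scaling by the spike-ins gave 70.8% higher. The count was 61 without control array 2, 197 without control array 3, 58 without control array 4, 61 without hydrogen water array 1, 55 without hydrogen water array 3 and 71 without hydrogen water array 4, and it ran from 25 to 505 over all settings tried.

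Among the genes that fell, Cish went from a log2 signal of 7.94 ± 0.38 in controls to 4.27 ± 0.52 with hydrogen water (SD, n = 4 each), a change of −3.67 ± 0.26 (SE; adjusted p = 0.00038). Its other probe set changed by −3.34 ± 0.33. Onecut1, a liver-enriched homeodomain factor also called HNF6, fell by 2.54 on the log2 scale (SE 0.47, adjusted p = 0.033) at a probe set that can bind several transcripts, and its second probe set, at −2.73 ± 0.57, did not pass (adjusted p = 0.0578). Rgs3, a regulator of G protein signalling, changed by −2.32 ± 0.31 (SE), Myc by −2.31 ± 0.32 and Hhex by −1.98 ± 0.18. Greb1l changed by −2.17 ± 0.43 and the uncharacterized LOC102549203 by −2.01 ± 0.34. Dusp1, a phosphatase that inactivates MAP kinases, changed by −1.88 ± 0.28 and by −1.80 ± 0.22 at a second probe set. Bhlhe40, a clock-linked repressor, changed by −1.36 ± 0.24 and Vgll4, a cofactor of TEAD factors, by −1.32 ± 0.20. The anti-apoptotic Bcl2a1 changed by −1.28 ± 0.25 and Zfp385b by −1.27 ± 0.23. Apart from the second probe set of Onecut1, these adjusted p-values from limma lay between 0.00038 and 0.0483. The hydrogen water signal of Greb1l was also below the median of all values, and Greb1l passed in 9 of 12 other settings. Bcl2a1 passed in 6 of 12, and missed the threshold under median, trimmed mean and spike-in scaling, without a pseudocount, without a filter and without a trend in the prior.

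Among the genes that rose, Fkbp5 went from a log2 signal of 6.71 ± 0.67 in controls to 9.43 ± 0.48 (SD, n = 4 each), a change of 2.73 ± 0.32 (SE; adjusted p = 0.0054), and its second probe set changed by 2.28 ± 0.33. Nr1d1 went from 4.04 ± 0.44 to 6.03 ± 0.27 (SD, n = 4 each; adjusted p = 0.0056). Edem1, which sends misfolded glycoproteins to degradation, rose by 1.96 ± 0.27 (SE), and Retreg1, a receptor for autophagy of the endoplasmic reticulum, by 1.53 ± 0.25. Pigu, a subunit of the transamidase that attaches lipid anchors to proteins, rose by 1.19 ± 0.12, and the rhomboid-family gene Rhbdd2 by 1.59 ± 0.20. Nr0b2, the nuclear receptor SHP that restrains bile acid synthesis, rose by 1.46 ± 0.29. The lipid droplet protein Cidea rose by 1.11 ± 0.14 and the trypsin inhibitor Spink1 rose 2.29-fold (adjusted p = 0.0399). Pcp4l1 rose by 1.48 ± 0.26, N4bp2l1 by 1.22 ± 0.19 and Znf750 by 1.18 ± 0.21. Over these 24 genes, 11 further probe sets were tested, all changed in the same direction and 6 passed. Cidea, Cish, Edem1, Fkbp5, Hhex, Myc, Nr1d1, Pigu, Rgs3 and Rhbdd2 passed in each of the 8 fits that left out an array, and the probe sets given first for the other 14 genes missed the threshold in 1 or more of them, although the second of Dusp1 passed in all 8. Of the first 10, Cidea alone missed it in the 12 or 13 other settings checked per gene, without normalization (adjusted p = 0.0609). Znf750 passed in 9 of 12 of these settings. The minimum fold, the rank product and fits with a covariate were not checked per gene. With array brightness as a covariate only 9 of the 128 probe sets passed, so not all of the first 10 genes did. The number of the 24 that passed was 15 without control array 1, 14 without control array 2, 13 without control array 4, 13 without hydrogen water array 3 and 14 without hydrogen water array 4.

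Immediate-early genes, which respond within minutes to growth factors and stress, were represented by 14 measured genes. Dusp1 and Myc fell, and the other 12 did not pass. The median change was −0.32 on the log2 scale, and the list as a whole missed the threshold (limma camera, adjusted p = 0.0584, or adjusted p = 0.496 with an estimated correlation). Adjusted over the list alone, 4 genes were lower, Dusp1, Dusp6, Gadd45g and Myc, and 1, Gadd45b, was higher. Gadd45b and Gadd45g, both growth arrest genes, differed by 1.12 ± 0.23 and −1.99 ± 0.49 (SE). Egr1 differed by 1.08 ± 0.46 and Jun by −0.81 ± 0.32, and neither passed. The list passed in 13 of 21 alternative fits, with adjusted p-values from 9.0e-05 to 0.145.

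Among 18 genes that follow growth hormone or differ between the sexes in rat liver, Cish fell and the other 17 did not pass. The STAT5 target Socs2 had a log2 signal of 8.51 ± 1.10 in controls and 5.38 ± 2.11 with hydrogen water (SD, n = 4 each), a difference of −3.13 ± 0.89 (SE; adjusted p = 0.149) that passed only when adjusted over the list alone, where 2 genes were lower. Igf1 and its binding partner Igfals differed by −0.20 ± 0.08 and −0.38 ± 0.15, and neither passed. The list's median was 0.00 and its mean −0.38, so that the median lay above 0 and the camera test pointed down, without passing (adjusted p = 0.424).

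Of 21 measured genes of the circadian clock, Nr1d1 rose, Bhlhe40 fell and 19 did not pass, over all probe sets as well as adjusted over the list alone. Nr1d2, the paralogue of Nr1d1, differed by 0.59 ± 0.20 (SE) and the clock-controlled Usp2 by 0.73 ± 0.23. The core activator Bmal1 differed by −0.05 ± 0.14 and the output factor Dbp by −0.27 ± 0.19, with adjusted p-values of 0.935 and 0.628. The list did not shift (camera adjusted p = 0.965), and its median of −0.05 and mean of 0.03 had opposite signs.

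Genes that act on reactive oxygen species showed no change that passed. None of 29 antioxidant enzyme genes passed over all probe sets in limma, 2 had an unadjusted p under 0.05, and 1, Glrx, a glutaredoxin, was higher when adjusted over the list alone, by 0.52 ± 0.11 (SE). The superoxide dismutases Sod1 and Sod2 differed by −0.02 ± 0.05 and 0.09 ± 0.09, catalase (Cat) by −0.10 ± 0.05 and glutathione peroxidase Gpx1 by 0.16 ± 0.06, the last with an adjusted p of 0.261. The sign of Sod1 turned under 4 scalings and that of Cat under 3 of them. Glutathione reductase (Gsr) differed by −0.14 ± 0.12. The list did not shift (camera adjusted p = 0.953), its median of −0.02 and mean of 0.01 had opposite signs, and the median turned positive under median, trimmed mean and spike-in scaling.

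Among 21 target genes of NRF2, the transcription factor of the oxidant response, 0 passed in limma, 0 had an unadjusted p under 0.05 and 0 passed over the list alone. Heme oxygenase Hmox1 differed by 0.14 ± 0.13 (SE) and Nqo1 by −0.10 ± 0.31. Osgin1, with the smallest p of the list, differed by −0.88 ± 0.51 (adjusted p = 0.540). Of 31 heat shock and unfolded protein response genes, 0 passed and 3 had an unadjusted p under 0.05. Atf4, a translationally controlled stress factor, was lower only when adjusted over the list alone, at −0.51 ± 0.10 (adjusted p = 0.0513 over all probe sets), and Xbp1 differed by −0.70 ± 0.20. Neither list shifted, with camera adjusted p-values of 0.953 and 0.946, and both medians, −0.01 for NRF2 targets and −0.02 for heat shock genes, turned positive under median and spike-in scaling.

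Cholesterol synthesis was measured through 20 genes, none of which passed in limma, over all probe sets or over the list alone, and 2 had an unadjusted p under 0.05. The median was 0.14 on the log2 scale (camera adjusted p = 0.252), and the list passed in 2 of 21 alternative fits, without normalization (adjusted p = 0.0152) and without control array 1 (0.00614). With an estimated correlation, used only on the quantile-normalized arrays, camera gave the list an adjusted p of 0.978. Squalene epoxidase Sqle differed by 0.72 ± 0.19 (SE) and the isomerase Idi1 by 0.82 ± 0.31. Of 23 genes of bile acid metabolism, Nr0b2 rose and Amacr, a racemase of bile acid side chains and branched fatty acids, fell by 0.56 on the log2 scale (SE 0.08, adjusted p = 0.0141). The other 21 did not pass, and adjusted over the list alone 2 were higher, Nr0b2 and Nr5a2, and 1 lower. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by −0.26 ± 0.44 (adjusted p = 0.871). Nr0b2 passed in 1 of the 8 fits that left out an array, that without control array 3, and missed the threshold without normalization, without a filter, with a filter that leaves out 75% of probe sets, without a trend in the prior and with gene means. Amacr missed it without control array 2 or 4, with spike-in scaling and without a trend.

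Of 36 targets of PPARA and genes of fatty acid oxidation, the peroxisome division factor Pex11a rose by 0.69 ± 0.12 (SE; adjusted p = 0.0319) and 35 did not pass, with Acot12 also higher when adjusted over the list alone. The hepatokine Fgf21 differed by −1.44 ± 0.52 and did not pass. None of 18 fatty acid synthesis genes passed in limma, 5 had an unadjusted p under 0.05, and Thrsp, a lipogenic thyroid hormone target, was higher over the list alone, by 1.32 ± 0.31 (adjusted p = 0.0801). Of 21 glucose genes, Foxo1, a transcription factor restrained by insulin, rose by 1.10 ± 0.21 (adjusted p = 0.0354) and 20 did not pass. Pfkfb1 was also higher over the list alone, by 0.65 ± 0.15. Camera gave adjusted p-values of 0.953 for the first of these lists, 0.720 for the second and 0.104 for the third. Pex11a missed the threshold without control array 1 or 2 or hydrogen water array 1, 3 or 4, and Foxo1 without these or control array 4. Both also missed it without normalization, without a trend in the prior and with gene means.

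Of 33 cytochrome P450 and xenobiotic genes, Alas1, the rate-limiting enzyme of heme synthesis, fell by 0.94 on the log2 scale (SE 0.18, adjusted p = 0.0405), and 32 did not pass. Adjusted over the list alone, the nuclear receptors Nr1i2 and Nr1i3 were higher, by 0.41 ± 0.11 and 0.45 ± 0.13, and Alas1 and Cyp17a1 lower. Of 25 acute phase and inflammation genes, Stat3, which carries interleukin signals to the nucleus, rose by 0.91 ± 0.15 (adjusted p = 0.0225), and 24 did not pass. Il1r1 and Vcam1 were also higher over the list alone, by 0.60 ± 0.14 and 0.67 ± 0.19. Camera gave an adjusted p of 0.950 for both lists, and the median of the second, −0.01, lay below 0 while its test pointed up. Both lists passed, pointing up, under median, trimmed mean and spike-in scaling, with adjusted p-values from 0.00348 to 0.0158 for the first and from 0.000894 to 0.00483 for the second. An estimated correlation was used only on the quantile-normalized arrays, where camera gave an adjusted p of 0.978 for each. Alas1 passed in 1 of the 8 fits that left out an array, that without hydrogen water array 2, and missed the threshold with spike-in scaling, with the 75% filter and without a trend in the prior. Stat3 missed it without control array 1 or 2 or hydrogen water array 1, 3 or 4, without normalization and without a trend.

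No single marker of a liver cell type passed in limma over all probe sets. The 5 measured markers of cholangiocytes, the cells that line bile ducts, had a median of −0.19 (camera adjusted p = 0.104), and the keratin Krt18, which hepatocytes also make, was lower when adjusted over the list alone, at −0.71 ± 0.15 (SE; adjusted p = 0.0576 over all probe sets). In 6 further cell type lists, for hepatocytes, Kupffer cells and macrophages, endothelial cells, stellate cells and fibroblasts, lymphocytes and erythroid cells, 0 of 78 list entries passed in limma and 7 had an unadjusted p under 0.05, with medians between −0.12 and 0.23 and camera adjusted p-values of 0.299 to 0.965. The hepatocyte list passed in 3 of 21 alternative fits (lowest adjusted p = 0.000192) and the erythroid list in 2 of 20 (0.0152). With an estimated correlation, used only on the quantile-normalized arrays, both had an adjusted p of 0.978. Medians and tests of the endothelial list, and mean and test of the lymphocyte list, differed in sign. The remaining 10 lists covered oxidative phosphorylation, ribosomal proteins, the proteasome, amino acids and the urea cycle, hypoxia, interferon response, conjugation, the cell cycle and both liver zones. There 0 of 242 list entries passed and 12 had an unadjusted p under 0.05, with medians between −0.06 and 0.02 and camera adjusted p-values of 0.406 to 0.965. Oxidative phosphorylation passed in 5 of 21 alternative fits (lowest adjusted p = 0.00020), amino acids and the urea cycle in 4 (0.0042) and ribosomal proteins in 3 (0.00238). Each had an adjusted p of 0.978 at an estimated correlation in the quantile-normalized arrays, and these alternative fits were not repeated with it. The medians of both zone lists and the means of both zone lists and the proteasome lay below 0 while their tests pointed up.

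Of the 30 lists tested, camera called 0 and 5 had an unadjusted p under 0.05, and with an estimated correlation it also called 0. The rotation test fry, which asks whether a list's genes move on balance one way, called 2, immediate-early genes and cholangiocyte markers, both lower with an adjusted p of 0.0455. Its mixed form, which asks whether members change in either direction, called 7, among them the growth hormone list (adjusted p = 8.8e-06), the clock (7.3e-05) and immediate-early genes (0.000201). Neither form compares a list with the other genes as camera does, so a call does not show that a list changed more than they did. Whether single members such as Cish and Nr1d1 carried these calls was not tested. Camera called 4 lists without normalization between arrays, 9 with each array centred on its median and 10 with trimmed mean or spike-in scaling, and up to 4 when an array was left out. The lists of bile acid and glucose genes passed, higher, under median, trimmed mean and spike-in scaling, and those of immediate-early genes and cholangiocyte markers passed, lower. With an estimated correlation, used only on the quantile-normalized arrays, camera gave them adjusted p-values of 0.978, 0.916, 0.496 and 0.505 in that order. At the preset correlation the same arrays gave 0.358, 0.104, 0.0584 and 0.104. The calls under the other scalings were not tested with an estimated correlation.

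**Figure D2:**
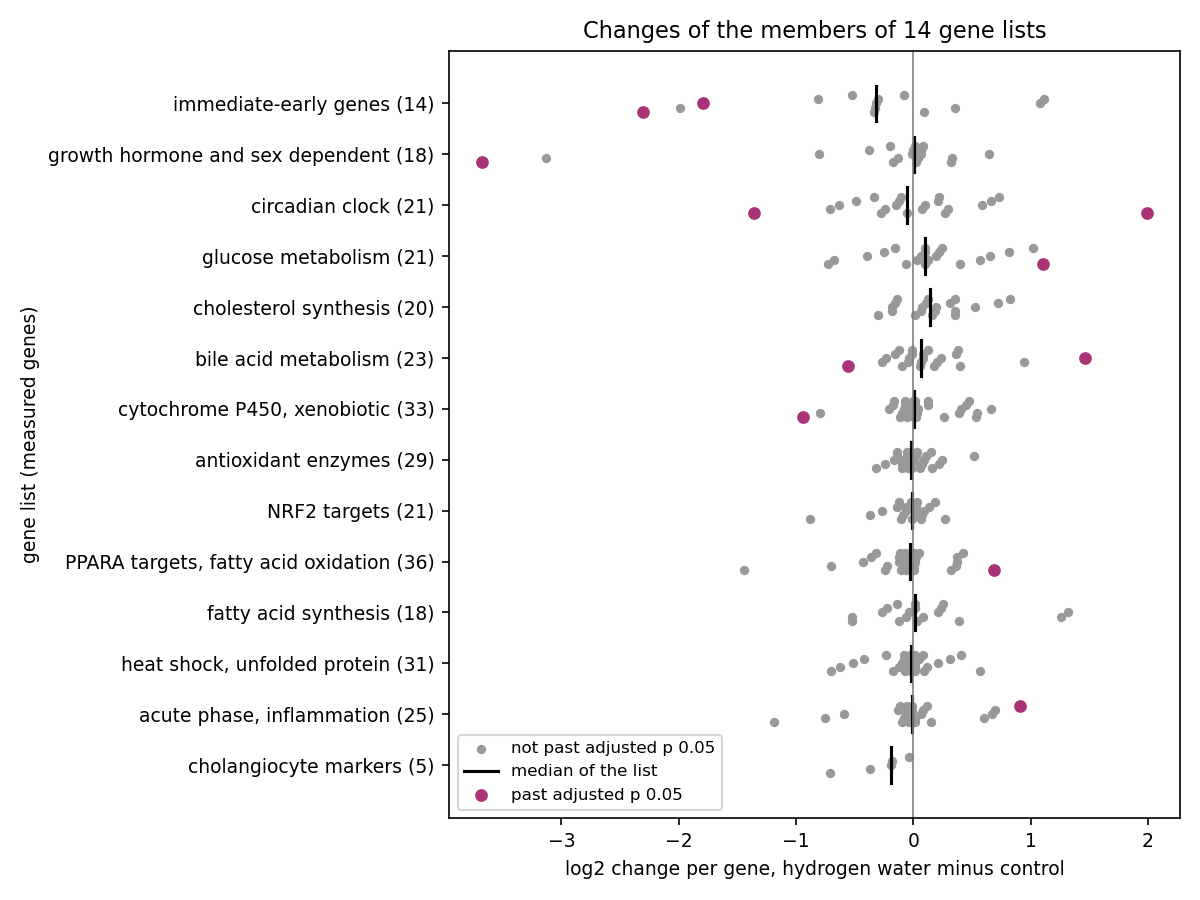
Log2 change of each measured gene (points, 1 per gene) in 14 gene lists, hydrogen water minus control, with genes past an adjusted p of 0.05 in purple and the median of each list as a black bar; the number of measured genes stands beside each list. List medians run from −0.32 for immediate-early genes to 0.14 for cholesterol synthesis, and no list passed camera.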

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

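The tests of array brightness by a split of the arrays, of the splits themselves and of the Gapdh ratio, and the indices without genes below the signal filter, were chosen after results were seen. A test for an array far from the other 3 of its group was run on 174 groups of 4, covering the named genes and 6 array measures. It picked out 10, where chance gives about 8.70.

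Edem1 stood at 9.68 on the log2 scale on hydrogen water array 2, below the other 3 arrays at 10.5 to 10.6, and still above each control. Greb1l stood at 2.18 on hydrogen water array 1, below the others at 4.05 to 4.39. Pcp4l1 stood at 6.10 on control array 2, above the others at 5.01 to 5.16, and Srxn1 at 7.17 on the same array, above 6.45 to 6.54. Control array 3 was apart for 3 genes, low for Hmox1 at 6.71 and Osgin1 at 9.42 and high for Foxo1 at 7.83. Dnajb9 stood at 8.80 on control array 4, above 8.17 to 8.23. The log2 3′ to 5′ ratio of beta-actin was 1.65 on control array 2, above 1.58 to 1.59, and 1.56 on hydrogen water array 1, below 1.66 to 1.67.

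The difference between the groups at 128 probe sets was weighed against chance, array brightness and RNA quality. The real grouping was 1 of 35 splits of the 8 arrays to give as many, the lowest share that 35 splits allow, and the highest other split gave 2. The split into the 4 brightest and 4 dimmest arrays gave 0 probe sets past the threshold. With brightness as a covariate the median change of the 128 was 101.3% of that without, and the median SE rose from 0.15 to 0.19. Only 12 probe sets passed, 9 of the 128 among them, for a cause that was not tested. With the Gapdh ratio as a covariate the median change was 108% of that without. The median SE also rose from 0.15 to 0.19, yet 239 probe sets passed, 68 of the 128 among them. The ratio itself differed by 0.16 ± 0.06 (SE), below the 0.3 set for a shift in RNA quality. Both covariate slopes come from the spread within groups, and the 128 were called for changes large against that spread. A large fall in the median change was therefore unlikely with either covariate. The brightness split is itself 1 of the 35 splits, so its 0 adds nothing to them. Brightness and RNA integrity thus stay undecided. Hydrogen water, any difference in the order or hour of sampling, and batches that the labels do not give also stay open.

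Lower Cish and Myc were weighed against growth hormone signalling at the moment of sampling and tissue handling. Growth hormone is released in pulses in male rats and induces Cish through STAT5, so a hypothesis is that hydrogen water livers were sampled with less STAT5 activity. In a test written before its result was seen, an index was taken of Socs2, Igf1, Igfals and Onecut1 minus the repressed Bcl6. It differed by −2.25 ± 0.63 (SE) on the log2 scale without overlap (p = 0.0286, exact permutation test, the smallest possible). Onecut1 is among the 24 genes picked from these data for their change, as are Cish and Myc, so this index is not an independent test. A version without Onecut1, not written beforehand, differed by −1.88 ± 0.51 (SE). Socs2, Igfals and Igf1 had the smallest p of the growth hormone list after Cish in these same data. The version without Onecut1 is therefore not an independent test either. Both index values point the way of that hypothesis, which may reflect the treatment or the timing of pulses. The value without Onecut1 rests on Socs2 at −3.13, whose groups overlapped, and Bcl6 at 0.64 (limma adjusted p = 0.557), while Igf1 and Igfals stood at −0.20 and −0.38. Handling stress in controls would lower other immediate-early genes with hydrogen water; Fos, Egr1, Jun, Atf3, Ier2 and Junb averaged −0.32 ± 0.27 (SE), which rests on Fos and Atf3, both below the signal filter, and the 4 others averaged 0.07 ± 0.29, so handling stays undecided.

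Higher Nr1d1 was weighed against the hour of sampling, since its transcript cycles strongly through the day. Clock genes that peak toward evening minus those that peak toward morning, without Nr1d1, differed by 0.31 ± 0.18 (SE; p = 0.171, exact permutation test), between the bound of 0.5 that a shift in hour would need and the 0.3 below which it would be excluded. With the 10 genes above the signal filter the difference was 0.43 ± 0.17 without overlap (p = 0.0286, exact permutation test, the smallest possible), still below 0.5. Nr1d2 at 0.59, Usp2 at 0.73, Hlf at 0.22 and Bhlhe41 at 0.07 point to a shift. So do the 5 morning genes, from −0.49 for Cry1 to −0.05 for Bmal1. Per3 at −0.44, Dbp at −0.27 and Tef at −0.15 point against it, with Per3 and Bhlhe41 below the signal filter. Bhlhe40 at −1.36, Per2 at −0.71, Cry2 at −0.64 and Por at 0.66 lay in neither set. Hour of sampling and hydrogen water cannot be told apart.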

How the results depend on the processing

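Trimmed mean and spike-in scaling were chosen after seeing the data. The count of 128 probe sets became 505 without normalization, where the median change of all tested probe sets was −0.33, 64 without a trend in the prior, 78 with gene means (9106 genes tested), 353 at a threshold of 0.10, 25 with a minimum fold of 1.2 and 229 with the rank product, whose calls were 35.6% false on simulated data. Leaving out each array gave 55 to 197, with fewer arrays in the fit. The other settings gave from 91, with a filter that leaves out 75% of probe sets, to 181, with the replicate number as a block, and scaling by spike-ins gave 144, 70.8% of them higher against 53.9%.

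The block also gave 1 list. Same-numbered arrays showed no clear tendency to deviate together (correlations of −0.10, 0.04, 0.19 and −0.003, and only 1 of 4 numbers matched best with itself). These 4 correlations cannot exclude that the numbers pair the arrays. Of the 24 genes, 12 of the 13 tested passed with the stricter filter, 13 of 24 without a trend, and 13 to 21 with an array left out. None of the 24 changed sign under any scaling. With an array left out none turned either, but their choice for groups without overlap all but fixed that in advance.

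Camera called 0 lists, against 4 without normalization, 9 with median centring, 10 with trimmed mean and 10 with spike-in scaling, 1 without a filter, 1 with the stricter filter, 1 with the block, 2 with fry and 0 to 4 with an array left out. The scalings by 1 factor per array might leave changes that depend on brightness. On each array the signals were taken as deviations from the mean of the probe set, and the median of the dimmest 10% was subtracted from that of the brightest 10%. This contrast differed between the groups of arrays by 0.028 ± 0.042 (SE) under trimmed mean scaling, which was undecided. That contrast cannot see a change that differs between the middle and the ends. Another measure is the median change per probe set. In groups of 10% by signal, numbered from the dimmest, it was −0.001, −0.044 and 0.043 for groups 1, 6 and 10 under trimmed mean scaling. With median centring it was 0.062, 0.002 and 0.082, and with quantile normalization −0.029, −0.001 and −2.7e-05. These values carry no SE, and their part in the list calls was not tested.

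Without normalization, where all probe sets moved by a median of −0.33, the raw changes of 7 genes that did not pass were negative, although each lay above that median: Sod2 −0.23, Gpx1 −0.044, Hmox1 −0.22, Pgd −0.15, Msrb1 −0.14, Cyp27a1 −0.075 and Dgat2 −0.027. Sod1 was 0.14 with median centring, 0.0075 with loess, 0.10 with trimmed mean and 0.17 with spike-in scaling, and Cat 0.047, 0.0086 and 0.073 with median centring, trimmed mean and spike-in scaling. With an array left out, Sod1 ran from −0.040 to 0.011 and turned without control array 2 or hydrogen water array 4. Nqo1 ran from −0.37 to 0.18 and turned without control array 3 or hydrogen water array 2, and Cyp7a1 ran from −0.64 to 0.19 and turned without control array 3. The 3′ to middle ratios differed by −0.031 for Gapdh and −0.061 for beta-actin, opposite in sign to the 3′ to 5′ ratios, with p = 0.371 for each (exact permutation test). The first principal component held 17.4% without a filter. Except where stated, the cause was not tested.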

Other observations

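The genes in the first paragraph were chosen after their values were seen, and the tests of Fkbp5 were written before the values of their gene sets were seen. Pcyt1a, the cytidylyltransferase of phosphatidylcholine synthesis, rose by 0.80 ± 0.12 (SE; limma adjusted p = 0.0139) and 0.68 ± 0.13 at its probe sets, and the choline kinase Chka, which acts just before it, fell by 1.06 (SE 0.20, adjusted p = 0.0402). The chemokine Cxcl12 changed by −0.73 ± 0.09 and the alarmin Il33 by −0.84 ± 0.12 at 1 probe set each, while further probe sets of Cxcl12, at −0.36 and −0.09, and of Il33, at −0.80, did not pass. The interferon-inducible GTPases Irgm and Irgm2 changed by −0.92 ± 0.17 and −0.53 ± 0.11. Dio1, the deiodinase that activates thyroid hormone in liver, rose by 0.88 ± 0.17. Stat3 rose at both of its probe sets, by 0.91 ± 0.15 and 0.77 ± 0.11. The fibrinogen gene Fga changed by −0.45 ± 0.07 at 1 probe set and by −0.08 ± 0.04 at another, which did not pass.

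Fkbp5 responds to glucocorticoids, so a hypothesis is that corticosterone was higher at sampling in hydrogen water rats. Tsc22d3, Sgk1, Klf9, Ddit4, Per1 and Mt2A, also induced by glucocorticoids, averaged a difference of 0.087 ± 0.20 (SE; p = 0.714, exact permutation test), too wide to decide, with Klf9 at 0.23 and Sgk1 at −0.26. A second hypothesis, a longer time since feeding, predicts that fasting genes rise against insulin-induced genes. The index of 6 fasting genes minus 6 insulin-induced genes differed by −0.12 ± 0.32 (SE; p = 0.743, exact permutation test). With the 11 of these genes above the signal filter it differed by −0.13 ± 0.32 (SE), a version chosen after the result was seen. Both values lie below the 0.3 under which the hypothesis was to be dropped. Their SE is wider than that bound, so the index cannot exclude a longer time since feeding. Pdk4 at −0.70 and Thrsp at 1.32 were opposite to fasting, and Igfbp1 at 0.82 and Ppargc1a at 1.02 in its direction.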
